A study of Mus musculus with 18 samples.

How the data were processed

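The study collected total RNA from C57BL/6 mouse sciatic nerve and DRG L3-L5 with no disease, at peak disease (PID21) and during recovery (PID42), and sequenced it in bulk after preparing mRNA libraries with a SMARTER kit, per the labels. How the disease was induced and what PID stands for are not given in the sources used here. Each of the 6 groups of 2 tissues and 3 stages held 3 libraries, and the labels name no batch. Library code numbers ran together within groups. The labels do not say whether the codes follow the order of processing, and if they do, that order cannot be separated from group. STAR 2.6.1a, kallisto 0.44.0 and Bowtie2 are listed with the builds GRCm38 and mm10, per the submitters' processing notes. The role of each tool, the counting step, the annotation and the strand setting are not given in the sources used here.

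The authors deposited raw read counts per Ensembl gene for 28684 genes in each of the 18 libraries, as whole numbers. A second deposited sheet gives a normalised signal, which was checked to be the counts times 1 constant per library (largest relative departure 5.11e-15 over genes with 50 or more counts). The authors' table of comparisons gives a log2 ratio of the first named group over the second, per the file headers. It also gives an adjusted p-value (q-value) per gene, per the file headers, whose method of adjustment is not given in the sources used here. The sheet of group means was not used here because the values per library were at hand. Fits here started from the counts, and the authors' q-values were used only to count their calls at q under 0.05.

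Gene names were read from the authors' sheets and positions from a copy of GENCODE vM21 on GRCm38, in which 28578 of the 28684 IDs were found and 27066 of these had the same symbol. Of 293 named genes, 37 have exons that overlap another gene of the table, so with the strand setting unknown their counts may include reads of that gene. Those named in the texts are Chchd10, Col5a1, Cxcl10, Fbn2, Shh and mt-Nd6. All 3 libraries of each group entered the analysis. Total counts per library ranged from 13686465 to 23435562, and TMM factors from 0.798 to 1.09. A gene with no count in the 3 libraries of a group was given a floor of 3 counts over that group, which is 0.0479 CPM in nerve at peak and 0.0511 CPM in nerve at recovery. Floors cover counting error only.

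Each tissue was fitted on its own 9 libraries in edgeR 4.0.16 under R 4.3.3, with filterByExpr, TMM normalisation and the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with adjusted p under 0.05 were called. The SE of a log2 fold change is its size divided by the square root of F. The tissue difference, the change from no disease to peak in nerve minus that in DRG, was tested as an interaction in 1 fit of all 18 libraries. Levels are TMM-scaled CPM within a tissue, except beside the tissue difference, where they are scaled over all 18 libraries. Principal components used log2 CPM with a prior count of 2 and the 500 most variable genes.

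The 37 gene lists cover Schwann cells, myelin and sterol synthesis, other glia, immune cells, vessels, connective tissue, muscle and blood, classes of sensory neurons, and cell states such as proliferation and injury. Lists with at least 3 members tested were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Each was also tested with an estimated correlation and with fry, which does not compare a list with other genes. Members called were counted over all genes and adjusted over the list alone. A macrophage or Schwann cell gene can also be expressed by other cells of these tissues, and several genes stand in more than 1 list.

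The comparisons, tests, thresholds, gene lists, alternatives and the rule for named genes were fixed before the data were examined, apart from the items named here as chosen later. The rule takes the 8 largest rises and 8 largest falls at peak and the 4 largest each way elsewhere. It takes them among genes with adjusted p under 0.05, a mean of at least 5 CPM and groups that do not overlap, leaving out predicted genes named Gm or Rik. It adds up to 4 members past the threshold with at least 1 CPM for each list described, or up to 3 abundant members where none passed, and 12 genes in every comparison. Of the genes it names, 4 stay in every fit and list test but are not reported here. For the tissue difference, the part on groups that do not overlap was read, after the data were seen, as applying in at least 1 tissue.

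The edgeR fit was tested on simulated data with 200 changed genes, spread over 1.5-fold, 2-fold and 4-fold changes. They were drawn from the more abundant genes, so the rates do not cover genes with low counts. Of 67 genes changed 2-fold, the fit recovered 73.1% in both nerve comparisons with no disease, 88.1% in DRG at peak and 92.5% in DRG at recovery. Of 67 changed 1.5-fold, it recovered 26.9% and 32.8% in nerve at peak and recovery, and 49.3% and 52.2% in DRG. False calls over all folds were 4, 11, 14 and 14 in that order. The overlap of peak and recovery calls was set against 20 simulations of unchanged groups that share their control libraries.

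Alternatives changed 1 choice at a time: RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 3 libraries, a replicate block, the compared groups alone, all 18 libraries in 1 fit, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and each library left out in turn. A fit without the 3 genes that hold ribosomal RNA reads and, in DRG, a fit with a blood score as a covariate were chosen after seeing the data. Counts of calls were also compared with other splits of the samples, the 10 splits of 6 libraries or 100 drawn splits. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.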

Results

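The data were bulk RNA sequencing counts from C57BL/6 mouse sciatic nerve, which carries sensory axons and their Schwann cells, and from dorsal root ganglia (DRG) L3-L5, which hold the cell bodies of sensory neurons. Each tissue was collected with no disease, at peak disease (PID21) and during recovery (PID42), with 3 libraries in each of 6 groups and 18 libraries in total. Total counts per library ranged from 13686465 in nerve no disease replicate 2 to 23435562 in nerve peak replicate 3. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples. The series title asks which types of sensory neuron are vulnerable when contact between axons and glia is lost. The comparisons therefore set peak and recovery against no disease in each tissue, recovery against peak, and the peak response of nerve against that of DRG. Levels are counts scaled to library size (CPM) as mean ± SD over 3 libraries, and changes are log2 fold changes ± SE from edgeR.

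In the principal components of the 500 most variable genes, nerve libraries separated by stage, with PC1 holding 63.4% and PC2 15.8% of the variance. For 9 of 9 nerve libraries the nearest other library was of the same group. DRG libraries separated less by group, with 37.5% on PC1, 24.3% on PC2 and the nearest library in the same group for 5 of 9. DRG recovery replicate 1 lay at 9.70 on PC1, near the no disease libraries at 10.7 to 21.1, whereas recovery replicates 2 and 3 lay at -19.6 and -16.1. The 3 genes that hold ribosomal RNA reads took 3.68% to 23.9% of counts in no disease nerve and 0.649% to 2.40% in peak nerve, and 4.03% to 16.1% in DRG.

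**Figure D1:**
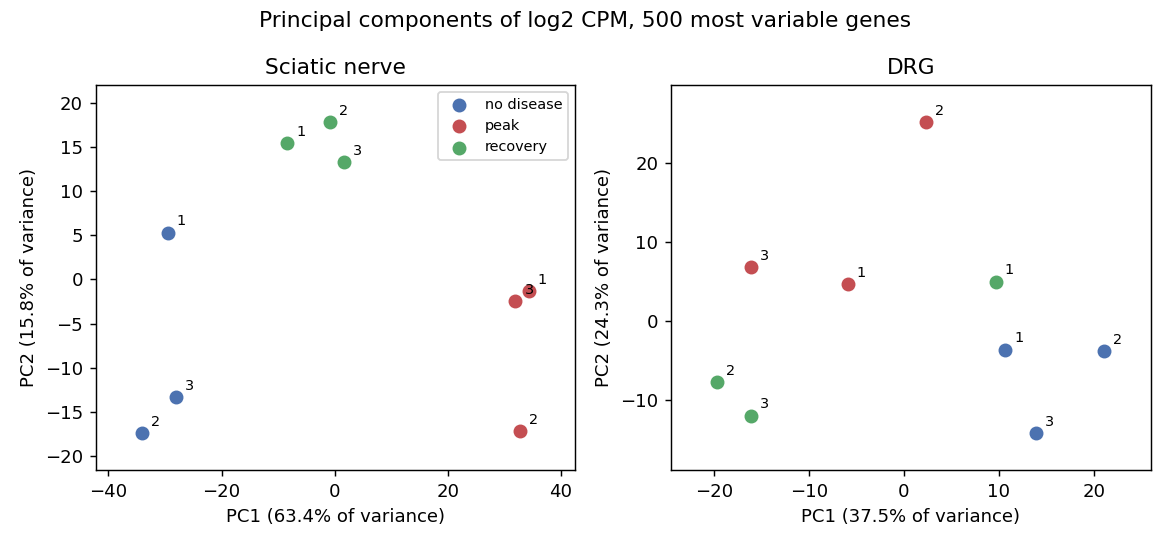
Principal components of the 500 most variable genes (log2 CPM) in nerve and in DRG, 9 libraries each; points are libraries, colours are stages and digits are replicate numbers. Nerve PC1 holds 63.4% of the variance, and DRG recovery replicate 1 lies at 9.70 on PC1, beside the no disease libraries.

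At peak disease the nerve held more transcripts of dividing cells, macrophages and repair Schwann cells than with no disease. Of 27 proliferation genes, 25 rose, also 25 when adjusted over the list alone, with a median log2 fold change of 3.02. Mki67 (ENSMUSG00000031004, GRCm38 chromosome 7, 135689784 to 135716361), a nuclear antigen of cycling cells, rose from 10.1 ± 2.32 to 104 ± 21.5 CPM (3.35 ± 0.19, adjusted p = 1.3e-05). The mitotic genes Ccnb1 (4.13 ± 0.28), Top2a (3.83 ± 0.21) and Cdk1 (3.83 ± 0.26) rose with it. Of 21 macrophage genes, 15 rose and 1 fell, or 17 and 2 adjusted over the list alone, with a median of 2.08. The lysosomal glycoprotein Cd68 (ENSMUSG00000018774, chromosome 11, 69664213 to 69666153) rose from 17.2 ± 3.02 to 110 ± 31.6 CPM (2.68 ± 0.21, adjusted p = 3.73e-05), beside the lipid receptor Trem2 (3.83 ± 0.27) and Gpnmb (3.85 ± 0.22). Of 14 genes of repair Schwann cells, 11 rose and 1 fell (11 and 2 over the list alone), among them the morphogen Shh (2.96 ± 0.63), the trophic factor Gdnf (2.68 ± 0.46) and Gfap (2.92 ± 0.46). Lipid handling genes rose in 11 of 17 cases (11 over the list alone), including the lysosomal protease Ctsd (2.57 ± 0.16) and Apoe (2.25 ± 0.21). Camera called these 4 lists higher, with adjusted p = 7.21e-41 for proliferation, 8.46e-24 for macrophage, 5.04e-07 for repair and 3.97e-12 for lipid handling. With an estimated correlation the adjusted p was 0.0478 for proliferation, 0.142 for macrophage, 0.105 for repair and 0.0478 for lipid handling. Splits of these libraries that mixed the stages called 13 to 17 lists, where the real one called 13. The number of lists called with the preset correlation thus does not show an effect of stage.

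Among single genes of peak nerve, the largest rise by the fixed rule was that of Wif1 (ENSMUSG00000020218, chromosome 10, 121033960 to 121100650), a secreted inhibitor of Wnt signalling. It went from 0.112 ± 0.0187 to 19.7 ± 2.49 CPM (7.35 ± 0.43, adjusted p = 1.32e-05). Cd22 (ENSMUSG00000030577), a sialic acid-binding receptor known from B cells, rose to 22.9 ± 7.66 CPM (6.49 ± 0.47, adjusted p = 2.73e-05), the cation channel Mcoln3 rose by 6.60 ± 0.52 and the proton pump subunit Atp6v0d2 by 4.83 ± 0.39. The macrophage elastase Mmp12 rose by 4.82 ± 0.68 to 16.4 ± 10.9 CPM, and the stress-induced transcription factor Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039) from 16.1 ± 2.88 to 49.5 ± 11.4 CPM (1.62 ± 0.19, adjusted p = 0.000343).

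Myelin genes as a group did not pass the test in peak nerve. Of 20 members, 2 rose and 1 fell, the same over the list alone, with a median of -0.17 (camera adjusted p = 0.558). The mean log2 CPM of the list was 8.22, 9.02 and 8.96 in no disease replicates 1, 2 and 3, and 8.80, 8.27 and 8.90 in peak replicates 1, 2 and 3. No disease replicate 1 and peak replicate 2 thus lay below the rest of their groups. Periaxin or Prx (ENSMUSG00000053198, chromosome 7, 27499324 to 27520214), a scaffold protein of myelinating Schwann cells, was at -0.59 ± 0.26 (adjusted p = 0.117), but was called lower without nerve no disease replicate 1 (0.0184), by DESeq2 and with all 18 libraries in 1 fit. Among the members that changed, the fatty acid carrier Pmp2 rose by 1.38 ± 0.20 and Drp2, a partner of periaxin, fell by 1.21 ± 0.12. Of 22 sterol synthesis genes, 8 fell (9 over the list alone), with the regulator Srebf2 at -1.02 ± 0.13 and a list median of -0.36 (-0.55 without peak replicate 3). Of 17 genes of fibroblasts and extracellular matrix, 11 rose and 2 fell (11 and 3 over the list alone), with Col1a1 at 1.43 ± 0.13 and Postn at 1.06 ± 0.14. The camera adjusted p was 9e-04 for sterol synthesis and 0.000424 for matrix genes, and with an estimated correlation the adjusted p was 0.647 and 0.579. The Schwann cell transcription factor Sox10 was at 0.03 ± 0.25 (adjusted p = 0.94), and its sign turned without no disease replicate 1 (-0.19) and without peak replicate 3 (-0.23).

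Transcripts of sensory neurons were lower in peak nerve. Of 14 pan-neuronal genes 9 fell (9 over the list alone), of 7 peptidergic genes 5 fell (7), and of 13 channels of sensory neurons 6 fell (8), with medians of -1.98, -2.62 (-1.36 without no disease replicate 1) and -0.81. Scn10a (ENSMUSG00000034533, chromosome 9, 119608456 to 119719322), a sodium channel of nociceptors, was at 12.9 ± 12.9 CPM with no disease and 0.125 ± 0.139 CPM at peak (-6.76 ± 1.20, adjusted p = 0.00311). Calca (ENSMUSG00000030669, chromosome 7, 114631478 to 114636357), which encodes the peptide CGRP, was at 25.4 ± 25.9 and 0.762 ± 0.273 CPM (-5.07 ± 0.98, adjusted p = 0.00487). With limma-voom the adjusted p was 0.0544 for Scn10a and 0.0545 for Calca, the highest over the alternatives, of which the lowest were 1.5e-07 and 1.27e-06. By camera the adjusted p was 0.000198 for pan-neuronal genes, 9e-04 for peptidergic genes and 0.000424 for channels, and with an estimated correlation the adjusted p was 0.612, 0.579 and 0.612. With fry the pan-neuronal (0.0922) and channel (0.0576) calls were lost. A set of 290 genes was chosen at 20 CPM or more in no disease DRG and at least 50 times their level in peak nerve. In the 3 no disease nerve libraries these genes stood at a median of 4.85%, 1.64% and 1.10% of their DRG level. They stood at 0.529% to 0.837% in peak nerve, a share held low by this choice, and at 0.756% to 2.33% in recovery nerve. Of 10 skeletal muscle genes 8 fell (10 over the list alone, camera adjusted p = 4.12e-06, and 0.579 with an estimated correlation), with the creatine kinase Ckm at -5.45 ± 0.98. Muscle genes held 0.0225% to 0.0692% of counts with no disease and 0.00117% to 0.00558% at peak. Muscle can be carried along at dissection, and whether these falls came from that was not tested. The calcium buffer Pvalb (ENSMUSG00000005716), found in fast muscle and in proprioceptive neurons, fell in nerve from 30 ± 25.3 to 1.87 ± 1.10 CPM (-4.03 ± 0.67, adjusted p = 0.00219).

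In nerve at peak, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2406 genes higher and 1949 lower of 16049 tested. The authors' table held 1809 higher and 1434 lower at q under 0.05, and 2955 genes were called in both with the same direction. Leaving out any of the 6 libraries gave 1658 to 2561 genes higher and 1320 to 2191 lower.

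**Figure D2:**
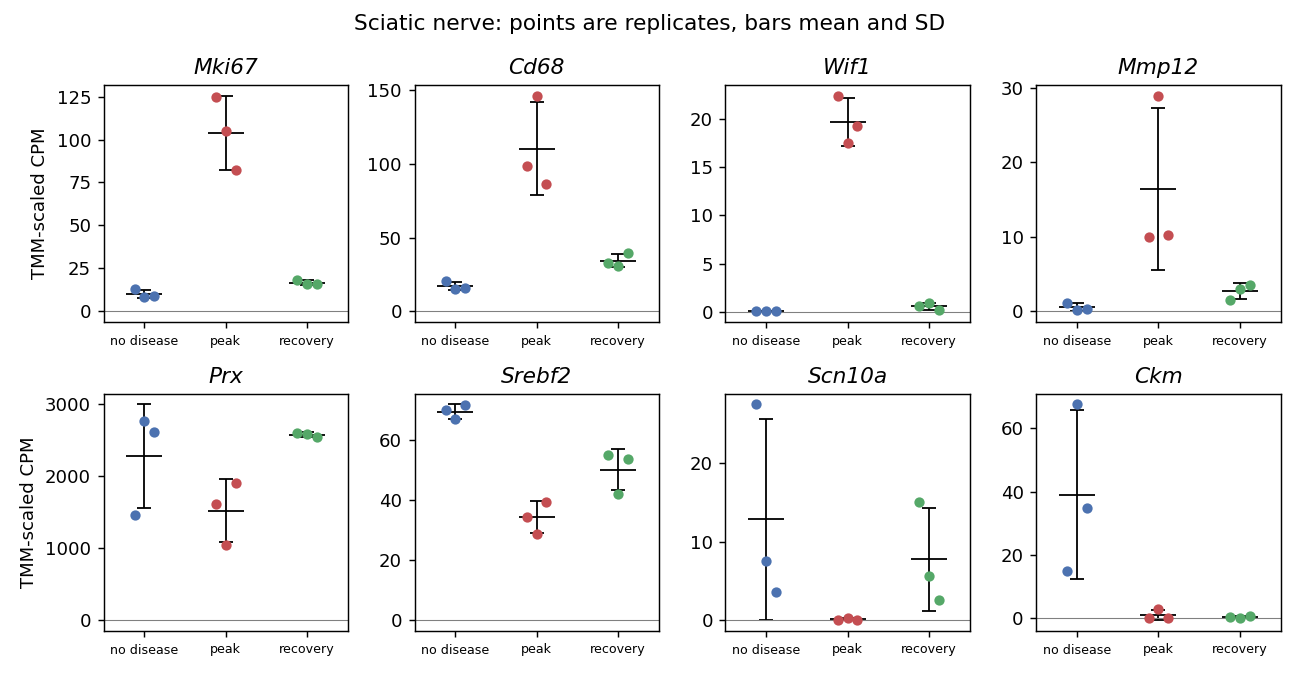
TMM-scaled CPM of 8 genes in sciatic nerve at each stage; points are replicates, bars are mean and SD of 3 libraries. Mki67 lies at 104 CPM at peak against 10.1 with no disease, while the no disease values of Scn10a spread from 3.55 to 27.5 CPM.

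During recovery the nerve held higher levels of a few immune genes than with no disease. Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889, exons shared with Art3), a chemokine induced by interferon, was at 19.2 ± 8.10 against 0.667 ± 0.261 CPM (4.77 ± 0.36, adjusted p = 0.00113). Mcoln3 (4.84 ± 0.55) and Cd22 (4.46 ± 0.50) also rose, each with adjusted p = 0.00622, but with limma-voom the adjusted p was 0.0558 and 0.064, the highest over the alternatives (lowest 2.67e-10 and 2.55e-14). Of 21 macrophage genes 5 rose, and 14 did when adjusted over the list alone, with a median of 0.80. Gpnmb rose by 1.81 ± 0.20 but lost its call without no disease replicate 2 (adjusted p = 0.0579, the highest over the alternatives, lowest 1.16e-14). Of 27 proliferation genes 2 rose (10 over the list alone, median 0.50), and of 17 lipid handling genes 1 rose (8, median 0.35, with 0.18 without no disease replicate 3 and 0.23 without recovery replicate 3). For these 3 lists camera gave adjusted p = 5.07e-23, 8.14e-12 and 1.43e-06, and with an estimated correlation the adjusted p was 0.147, 0.198 and 0.147. Mki67 was at 0.72 ± 0.19 (adjusted p = 0.13) and Cd68 at 1.00 ± 0.21 (adjusted p = 0.0593).

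Muscle transcripts were also lower in recovery nerve, where 8 of 10 members fell (10 over the list alone, median -5.80) and the muscle share was 0.0014% to 0.0021% of counts. Myoglobin (Mb) had 0 counts at recovery, which put it at least 145-fold below no disease (13-fold without no disease replicate 2, 90.1-fold without recovery replicate 3), and the list median was the same with Mb at that bound. Camera gave adjusted p = 5.07e-23 for the list, and 0.147 with an estimated correlation. Ckm fell by 6.82 ± 1.11 (adjusted p = 0.029) but was not called without no disease replicate 2 (0.111), no disease replicate 3 (0.0746), recovery replicate 1 (0.118), recovery replicate 2 (0.148) or recovery replicate 3 (0.115). None of 14 pan-neuronal genes passed edgeR's test, with 3 lower at unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Camera called that list lower (median -0.96, adjusted p = 0.000805, and 0.549 with an estimated correlation), but not without no disease replicate 1 (median -0.07, adjusted p = 0.57), and the median was -1.45 and -0.64 without recovery replicates 1 and 3. No disease replicate 1 was also the library that held the genes abundant in DRG at the highest share of their DRG level, 4.85%. Myelin genes were not called as a group (median 0.16, camera adjusted p = 0.0759), and none of 20 passed edgeR's test, with 2 higher and 1 lower at unadjusted p under 0.05, 1 and 1 by DESeq2 and 0 by limma-voom. Prx was at 0.18 ± 0.25 (adjusted p = 0.835) and turned to -0.06 without no disease replicate 1.

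In recovery nerve, 101 genes were higher and 63 lower than with no disease of 16049 tested. DESeq2 called 283 and 267, and limma-voom 55 and 35. The authors' table held 310 and 343, with 162 genes called in both in the same direction. Both counts fell in most fits with 1 library left out. Without no disease replicate 2 they were 13 and 4, and without no disease replicate 3 they were 19 and 9. Without recovery replicate 1, 2 or 3 they were 19 and 7, 15 and 1, and 15 and 0. Such fits have less power, so a lower count does not show that the library left out drove the calls.

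From peak to recovery, the genes of dividing cells, macrophages and matrix fell in nerve. Of 27 proliferation genes 23 fell (24 over the list alone, median -2.18), with Mki67 at -2.63 ± 0.18 (adjusted p = 6.31e-05). Of 21 macrophage genes 15 fell (15), with Cd68 at -1.68 ± 0.20 (adjusted p = 0.000766), and of 17 matrix genes 10 fell and 1 rose (12 and 1), with Col1a1 at -2.39 ± 0.13. Of 17 lipid handling genes 8 fell (10), with Ctsd at -1.86 ± 0.15. Wif1 fell by 5.05 ± 0.33, the secreted protein Cthrc1 (ENSMUSG00000054196) by 4.31 ± 0.30 and the microfibril gene Fbn2 by 3.52 ± 0.16. The 4 lists had camera adjusted p = 6.62e-37, 2.41e-11, 2.95e-11 and 3.04e-08, and with an estimated correlation the adjusted p was 0.103, 0.444, 0.226 and 0.112. Of 15 antigen presentation genes 6 rose (6, median 0.66, or 0.31 without recovery replicate 3, camera adjusted p = 5.65e-05, and 0.607 with an estimated correlation), with Cd74, the invariant chain of class II molecules, at 1.17 ± 0.20 and H2-Eb1 at 1.15 ± 0.20. Of 13 channels of sensory neurons 5 rose (7, median 0.78, camera adjusted p = 0.00273, and 0.607 with an estimated correlation), with Scn10a at 6.01 ± 1.21 (adjusted p = 0.00976, and 6.72e-06 to 0.094 over the alternatives, the highest with limma-voom). In the recovery libraries the genes abundant in DRG stood at a median of 2.33%, 1.23% and 0.756% of their DRG level. The last lies within the range of peak nerve, 0.529% to 0.837%.

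Between peak and recovery nerve, 1181 genes rose and 1785 fell of 16049 tested. The authors' table held 1117 and 1604, with 2231 called in both in the same direction. The count of rising genes was 758 without peak replicate 1, 683 without peak replicate 2, and 512, 429 and 664 without recovery replicates 1, 2 and 3. The count of falling genes was 901, 819 and 1145 without those 3 recovery libraries.

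In DRG at peak, genes of injured sensory neurons, of macrophages and of myelin were higher than with no disease. Of 18 neuronal injury genes 15 rose (18 over the list alone). Atf3 rose from 9.28 ± 1.91 to 126 ± 42.6 CPM (3.76 ± 0.26, adjusted p = 0.000245), Sprr1a (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895), a protein induced in regenerating neurons, from 0.236 ± 0.223 to 15.2 ± 7.04 CPM (5.95 ± 0.62, adjusted p = 0.00136), and the neuropeptide Npy (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507) from 0.42 ± 0.249 to 11 ± 6.34 CPM (4.69 ± 0.55, adjusted p = 0.00217). The orphan receptor Gpr151 (3.52 ± 0.34), the steroid transport protein Star (3.18 ± 0.23) and the neuropeptide Nts (2.88 ± 0.15) rose as well. Of 20 myelin genes 16 rose (19, median 0.83). Prx rose from 348 ± 73.5 to 687 ± 50.3 CPM (0.98 ± 0.14, adjusted p = 0.00491), and the adhesion molecule Mag by 1.24 ± 0.13. Myelin genes held 0.443% to 0.629% of counts with no disease and 0.966% to 1.01% at peak. Of 21 macrophage genes 15 rose (18, median 1.44), with Cd68 from 1.68 ± 0.53 to 8.35 ± 2.15 CPM (2.31 ± 0.35, adjusted p = 0.00586) and Trem2 at 2.77 ± 0.23. Of 17 matrix genes 8 rose (12, median 0.91), with the collagen Col5a1 at 1.35 ± 0.10. Camera gave adjusted p = 6.13e-49 for injury, 8.54e-25 for myelin, 3.48e-26 for macrophage and 1.1e-10 for matrix genes, and with an estimated correlation the adjusted p was 0.0985, 0.271, 0.271 and 0.404. With fry the matrix call was lost (0.0754).

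Some genes of sensory neuron classes fell in peak DRG. Pvalb (chromosome 15, 78191114 to 78206400) fell from 54.1 ± 16.4 to 17.6 ± 5.29 CPM (-1.62 ± 0.24, adjusted p = 0.00586). Muscle genes held 0.0272% of counts in no disease replicate 3 against 0.000466% to 0.00181% in the other no disease and the peak libraries, so muscle may add to Pvalb there, but replicates 1 and 2 were at 39.8 CPM or more against at most 23.4 CPM at peak, and Pvalb was also called without replicate 3. Among 8 genes of low-threshold mechanoreceptors, the calcium-binding proteins Necab2 (-1.12 ± 0.16) and Calb1 (-0.86 ± 0.10) fell, although Calb1 was not called with all 18 libraries in 1 fit (adjusted p = 0.0976, lowest over the alternatives 6e-10), and 1 rose and 2 fell over the list alone (median -0.24, and -0.15, -0.46 and -0.06 without no disease replicate 2, peak replicate 1 and peak replicate 3). Of 13 genes of large-diameter neurons 3 fell (3, median -0.35), of 19 non-peptidergic nociceptor genes 1 fell (4, median -0.24), and of 7 genes of C-fibre mechanoreceptors and cold sensors 1 fell (3, median -0.26). None of 10 peptidergic genes passed edgeR's test (2 fell over the list alone, median -0.30), with 4 lower at unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. Camera called lower the large-diameter (adjusted p = 0.000811), peptidergic (0.0076), non-peptidergic (0.00771), low-threshold (0.0267) and C-fibre (0.0268) lists. With an estimated correlation the adjusted p was 0.698, 0.306, 0.479, 0.404 and 0.444. The low-threshold call was lost without peak replicate 3 (adjusted p = 0.122), and the C-fibre call without no disease replicate 2 (0.0742) or peak replicate 2 (0.0851). With a blood score (erythroid and neutrophil lists) as a covariate the low-threshold (0.136), C-fibre (0.0708) and non-peptidergic (0.0708) calls were lost, and with fry those of the large-diameter (0.253), low-threshold (0.0754), C-fibre (0.063) and non-peptidergic (0.0754) lists. Pan-neuronal genes moved by a similar median (-0.24), with 3 of 14 lower (5 over the list alone, camera adjusted p = 0.0125, and 0.722 with an estimated correlation). That call was lost without peak replicates 1 and 3 (0.0687 and 0.0644), with the blood score (0.136) and with fry (0.275). Of 7 proprioceptor genes 1 rose and 1 fell (1 and 2 over the list alone, camera adjusted p = 0.4). Calca was at -0.32 ± 0.10 (adjusted p = 0.0654), the receptor Mrgprd (ENSMUSG00000051207) of non-peptidergic nociceptors at -0.35 ± 0.10 (adjusted p = 0.0545) and the neuronal tubulin Tubb3 at -0.05 ± 0.12 (adjusted p = 0.826), which turned to 0.03 without peak replicate 1. Whether these classes differed from one another in their change was not tested.

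In DRG at peak, 728 genes were higher and 529 lower of 16482 tested. Chchd10, a mitochondrial protein (-1.02 ± 0.09, adjusted p = 0.00044), and the lectin Clec2l (-1.13 ± 0.17) were among the falls that passed in each of the 6 fits with a library left out. The authors' table held 986 and 548, with 1021 called in both in the same direction. The counts were 195 and 119 without no disease replicate 1, 328 and 268 without replicate 2, and 281 and 128 without replicate 3. They were 473 and 265, 429 and 307, and 417 and 180 without peak replicates 1, 2 and 3.

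**Figure D3:**
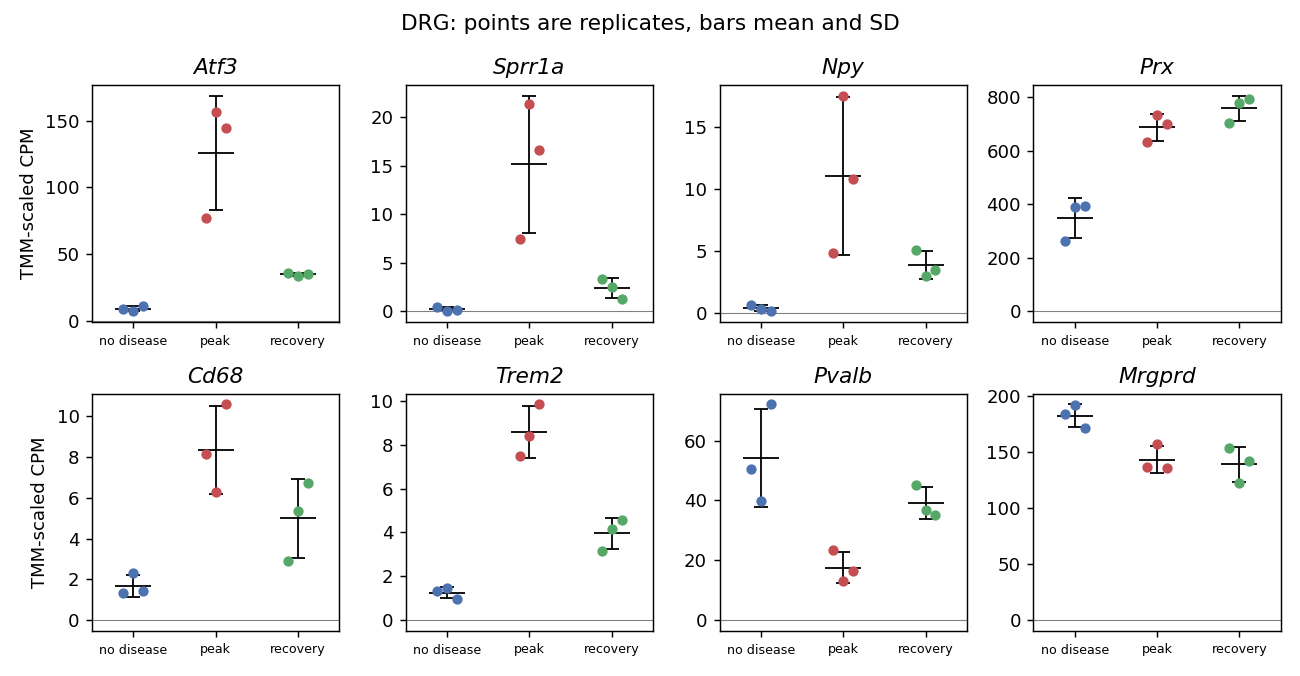
TMM-scaled CPM of 8 genes in DRG at each stage; points are replicates, bars are mean and SD of 3 libraries. Atf3 lies at 126 CPM at peak, 35.1 at recovery and 9.28 with no disease, and Prx at 687, 757 and 348.

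During recovery the DRG held higher myelin, macrophage and injury transcripts than with no disease. Of 20 myelin genes 14 were higher (19 over the list alone, median 0.94), with Prx at 757 ± 47.4 CPM (1.12 ± 0.14, adjusted p = 0.0116), and the myelin share was 0.898% to 1.24% of counts. Of 21 macrophage genes 11 were higher (19, median 1.14), with Trem2 at 1.66 ± 0.23. Of 18 injury genes 8 were higher (11, median 0.80), with Atf3 at 35.1 ± 1.01 CPM (1.92 ± 0.25, adjusted p = 0.0116). Of 15 antigen presentation genes 9 were higher (13, median 0.93), and of 15 cytokine genes 4 (10, median 1.17, or 1.76 without no disease replicate 3). Gadd45b, a stress-induced growth regulator, rose by 2.03 ± 0.21 (adjusted p = 0.00965), and the endothelin receptor Ednrb fell by 0.93 ± 0.12 (adjusted p = 0.0116). Of 19 non-peptidergic nociceptor genes 4 were lower (11, median -0.30). Camera also called lower the pan-neuronal (median -0.23, adjusted p = 2.24e-05), channel (-0.23, 2.88e-05), large-diameter (-0.21, 0.000872) and peptidergic (-0.28, 0.00164) lists, with an estimated correlation at adjusted p = 0.381, 0.381, 0.43 and 0.222. Without recovery replicate 1 the median was -0.36 for pan-neuronal, -0.49 for channel and -0.54 for large-diameter genes, while the channels were at -0.14 without recovery replicate 3 and the large-diameter genes at -0.11 without recovery replicate 2. Of their members 1 channel passed edgeR's test, while 8, 5, 4 and 3 members were lower at unadjusted p under 0.05, DESeq2 called 5, 3, 1 and 2 and limma-voom 1 channel. With fry the pan-neuronal (0.109), channel (0.136) and large-diameter (0.233) calls were lost, and with the blood score the large-diameter call (0.0712). Pvalb, which fell at peak, was at -0.47 ± 0.23 (adjusted p = 0.261), and Mrgprd at -0.39 ± 0.10 (adjusted p = 0.0564). Camera gave adjusted p = 5.16e-28 for myelin, 2.64e-19 for macrophage, 3.65e-13 for injury, 7.13e-14 for antigen presentation, 1.77e-10 for cytokine and 6.6e-08 for non-peptidergic genes. With an estimated correlation the adjusted p was 0.222 for each of these 6 lists.

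The calls in recovery DRG were not stable when 1 library was left out. A fit with fewer libraries has less power, so a lower count does not show that the library left out drove the calls. Of 16482 tested genes 402 were higher and 121 lower, and DESeq2 called 918 and 588. The authors' table held 756 and 126, with 440 called in both in the same direction. Without no disease replicates 1, 2 and 3 the counts were 2 and 0, 2 and 1, and 42 and 9, and without recovery replicates 2 and 3 they were 4 and 0, and 5 and 2. Without recovery replicate 1 they were 1758 and 1864. Adjusted p without no disease replicates 1 and 2 and recovery replicates 2 and 3 was 0.0735, 0.0645, 0.0647 and 0.0519 for Atf3, and 0.0735, 0.0642, 0.0749 and 0.0631 for Trem2. The call was also lost for Prx without no disease replicate 2 (0.0581), recovery replicate 2 (0.0647) and recovery replicate 3 (0.0519), for Ednrb without no disease replicate 1 (0.0727), recovery replicate 2 (0.0647) and recovery replicate 3 (0.0519), and for Gadd45b without no disease replicates 1 and 2 (0.0645 and 0.0506). Genes of blood cells also differed within this group: the erythroid list held 0.00493% of counts in recovery replicate 1 against 0.0594% and 0.0386% in replicates 2 and 3, and the neutrophil list 0.00917% against 0.0747% and 0.0637%. Camera called higher than with no disease the lists of B cells (median 1.46, adjusted p = 0.000578), neutrophils (1.31, 0.00367), erythroid cells (1.53, 0.0257) and T and NK cells (0.98, 0.0373). Of 8, 10, 5 and 7 members only 1, a B cell gene, passed edgeR's test (3, 0, 0 and 2 over the list alone). At unadjusted p under 0.05, 5, 3, 4 and 4 were higher, DESeq2 called 3, 2, 0 and 1, and limma-voom none. The 4 list calls were lost with an estimated correlation (adjusted p = 0.381, 0.474, 0.464 and 0.419) and with fry (0.117, 0.293, 0.292 and 0.136). Without recovery replicate 2 the median and adjusted p were 0.82 and 0.0607 for neutrophil, 0.96 and 0.17 for erythroid, and 0.55 and 0.183 for T and NK cell genes. The erythroid call was also lost without no disease replicate 2 (0.0869) and the T and NK cell call without recovery replicate 3 (0.0568), with a T and NK cell median of 1.499 without recovery replicate 1. With the blood score, which is built from the erythroid and neutrophil lists, the erythroid (0.886) and T and NK cell (0.375) calls were lost and the neutrophil median was -0.01.

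From peak to recovery in DRG, injury genes fell. Of 18 members 5 fell (15 over the list alone, median -0.99, camera adjusted p = 6.1e-33, and 0.194 with an estimated correlation), with Atf3 at -1.85 ± 0.23 and Gpr151 at -2.67 ± 0.31, each with adjusted p = 0.0286. The LIM-domain protein Csrp2 (ENSMUSG00000020186) fell by 1.46 ± 0.14 (adjusted p = 0.0187), and Chchd10 rose by 0.70 ± 0.09 (adjusted p = 0.0286). Of 15 antigen presentation genes 2 rose (7, median 0.46, camera adjusted p = 5.66e-13, and 0.439 with an estimated correlation). Myelin genes were not called (median 0.01, camera adjusted p = 0.729), and none of 20 passed edgeR's test, with 1 higher and 1 lower at unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. Prx was at 0.14 ± 0.14 (adjusted p = 0.662), and Pvalb at 1.15 ± 0.24 (adjusted p = 0.101). Csrp2 lost its call without recovery replicate 2 (adjusted p = 0.184). Without peak replicates 2 and 3 and recovery replicates 2 and 3 the adjusted p was 0.105, 0.0895, 0.186 and 0.137 for Atf3, 0.105, 0.0895, 0.186 and 0.115 for Gpr151, and 0.105, 0.0987, 0.186 and 0.0656 for Chchd10. Over the alternatives the lowest adjusted p was 4.2e-12 for Atf3, 4.57e-13 for Gpr151, 1.86e-06 for Chchd10 and 3.31e-16 for Csrp2, and with the compared groups alone it was 0.18, 0.18, 0.18 and 0.093.

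Between peak and recovery DRG, 5 genes were higher and 18 lower of 16482 tested, and 2372 had an unadjusted p under 0.05. DESeq2 called 101 and 191 and limma-voom 1 and 11, and the authors' table held 43 and 98, with 23 called in both in the same direction. The counts were 1 and 30 without peak replicate 1, 0 and 1 without peak replicate 2, 0 and 2 without peak replicate 3, 0 and 0 without recovery replicate 2, and 0 and 2 without recovery replicate 3. Without recovery replicate 1 they were 579 and 1175.

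**Figure D4:**
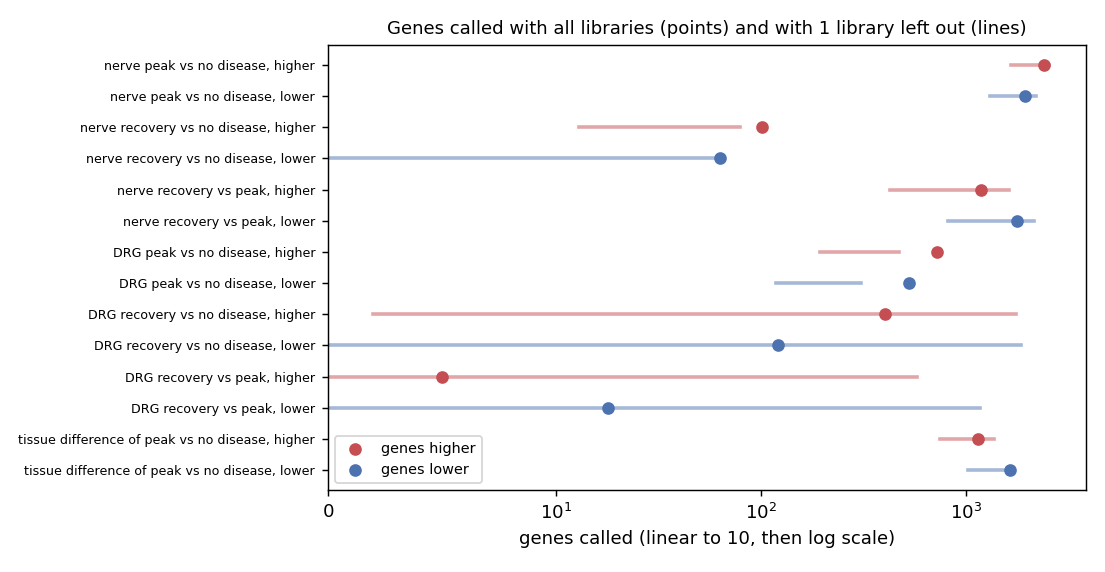
Number of genes called higher and lower in each comparison (axis linear to 10, then logarithmic); points are the counts with all libraries, lines the range when 1 library is left out. The lines are short for nerve at peak (1658 to 2561 genes higher) and long for DRG at recovery (2 to 1758).

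The tissue difference set the change from no disease to peak in nerve against the same change in DRG, over all 18 libraries. Proliferation genes rose more in nerve, with 17 of 27 members passing (18 over the list alone, median difference 1.84), and Mki67 differed by 2.23 ± 0.46 (adjusted p = 0.00487). Cthrc1 differed by 4.42 ± 0.37 (adjusted p = 4.21e-06), going from 2.45 to 43.6 CPM in nerve and from 5.45 to 4.53 CPM in DRG. Lipid handling genes were higher in nerve for 8 of 17 members (9 and 1 lower over the list alone), with Ctsd at 2.59 ± 0.18. Myelin genes went the other way, with 12 of 20 members lower in nerve than in DRG relative to no disease (14, median -1.04), and Prx differed by -1.60 ± 0.31 (adjusted p = 0.00327). Neuronal injury genes had a lower change in nerve than in DRG for 11 of 18 members (12, median -2.14). In nerve their mean log2 CPM was 2.82 with no disease and 2.81 at peak over the 14 members tested there. In DRG it rose from 3.00 to 4.98 over 18 members. Sprr1a had no count in either of these nerve groups, so its change there cannot be measured. Atf3, which rose in both tissues, differed by -2.19 ± 0.33 (adjusted p = 0.000644). Channels of sensory neurons were lower in nerve for 8 of 14 members (11, median -1.25), with Scn10a at -6.81 ± 1.26 (adjusted p = 0.00244), at 0.118 and 12.8 CPM in peak and no disease nerve and 747 and 771 CPM in DRG. Camera gave adjusted p = 1.05e-16 for proliferation, 2.49e-08 for lipid handling, 4.36e-07 for myelin, 1.68e-08 for injury and 8.7e-06 for channels, and with an estimated correlation the adjusted p was 0.217, 0.106, 0.587, 0.217 and 0.587. Macrophage genes were higher in nerve for 4 of 21 members and lower for 1 (5 and 1, median 0.33, camera adjusted p = 0.00525, 0.664 with an estimated correlation and 0.241 with fry). The macrophage median was 0.55 and 0.21 without nerve no disease replicates 1 and 2, 0.12 without nerve peak replicate 2, and 0.17 and 0.56 without DRG peak replicates 2 and 3. Cd68 rose in both tissues, and its difference was 0.33 ± 0.44 (adjusted p = 0.644).

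In this difference, 1146 genes were higher and 1637 lower in nerve of 17289 tested. The authors' table held 2507 genes at q under 0.05 for condition by tissue. Without DRG no disease replicate 3 the first count was 752, and without DRG no disease replicate 1 the second was 1028. At peak, 297 genes were higher in both tissues, where independent lists would share 106, and 122 were lower in both (60.1), over 15254 genes tested in both, an excess that was not itself tested. A further 35 genes were higher in nerve and lower in DRG, and 45 lower in nerve and higher in DRG.

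The genes called at recovery overlapped those called at peak. In nerve, 88 genes were higher and 52 lower at both stages, where independent lists would share 15.1 and 7.65, and 3 were called in opposite directions. In DRG, 256 were higher and 70 lower at both stages (17.8 and 3.88), and no gene was called in opposite directions. In 20 simulations of unchanged groups with the same 3 control libraries, edgeR called at most 2 genes per comparison, so their shared count of 0 says little. The log2 fold changes of peak and recovery correlated across genes, which are not independent replicates, at r = 0.645 in nerve and 0.69 in DRG, against 0.52 and 0.508 in the simulations. Their covariance was 0.264 in nerve and 0.129 in DRG against a simulated 0.0409 and 0.0319, which leaves 0.223 and 0.0971 beyond the simulated value. The simulations are not shown to hold shifts of many genes at once in a control library. Such shifts, as in the neuronal genes of nerve no disease replicate 1, would enter both comparisons. The remainder can therefore not be told apart from an effect of the shared controls. Part of the excess of shared calls may come from the shared control libraries. The nerve overlap of 140 genes was 15 without no disease replicate 2, 24 without no disease replicate 3, 91 without peak replicate 1, 247 without peak replicate 2, and 20, 13 and 12 without recovery replicates 1, 2 and 3. The DRG overlap of 326 genes was 2, 3 and 36 without no disease replicates 1, 2 and 3, 145 without peak replicate 3, 1251 without recovery replicate 1, and 4 and 6 without recovery replicates 2 and 3.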

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

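The tests of the 3 patterns and the counts over other splits of the samples were chosen only after the results were seen, whereas the test of the tissue difference was set beforehand.

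The responses of nerve and DRG to peak disease differed by the interaction test for 1146 genes higher and 1637 lower in nerve. Of 100 drawn splits of the labels within tissues, the real one included, 2 gave as many genes as the real 2783, both with the nerve labels kept. With the nerve labels kept, 8 splits that mixed the DRG labels called 1340 to 2543 genes, and the highest other split, which exchanged them, called 4303. With the nerve labels mixed, 90 splits called 0 to 20. Only 10 splits kept the nerve labels, and 2 of these 10 reached the real count, so the splits do not exclude chance for a difference between the tissues. The same splits gave as many lists as the real 20 in 8 of 100 cases, with a highest of 22, so for the number of lists chance is not excluded.

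By list, the median log2 difference (nerve minus DRG) was 1.84 for proliferation, 0.716 for repair Schwann cells, 0.404 for lipid handling, 0.332 for macrophages, 0.324 for mitochondrial RNA and -0.191 for satellite glia. The satellite glia list was called higher in nerve although its median was below 0, with Kcnj10 at 3.47 ± 0.27 and Apoe at 2.15 ± 0.27. The median was -0.386 for sterol synthesis, -0.469 for perineurial cells, -0.607 for antigen presentation, -0.865 for endothelium, -0.878 for nodes and paranodes, -1.04 for myelin and -1.05 for non-peptidergic nociceptors. It was -1.25 for channels of sensory neurons, -1.71 for cytokines, -1.99 for pan-neuronal genes, -2.14 for neuronal injury, -2.90 for erythroid cells, -3.04 for peptidergic neurons and -3.70 for neutrophils. The fit of nerve alone tested 5 neutrophil, 7 peptidergic and 14 injury members, against 10, 10 and 18 in DRG. The medians of these lists may thus rest in part on genes with few counts in nerve. The neutrophil list was not called in nerve at peak. Leaving out 1 library moved some of the list medians given above by over 1.5 times. Without nerve no disease replicate 1 the median was 0.777 for lipid handling, 0.552 for macrophages, -0.390 for antigen presentation, -0.626 for non-peptidergic, -1.16 for pan-neuronal, -1.86 for erythroid, -1.74 for peptidergic and -1.97 for neutrophil genes. Lipid handling was at 0.680 and 0.653 without DRG no disease replicates 2 and 3. Macrophages were at 0.213 without nerve no disease replicate 2, 0.123 without nerve peak replicate 2, and 0.169 and 0.557 without DRG peak replicates 2 and 3. Mitochondrial RNA was at 0.179, 0.208 and 0.165 without DRG no disease replicate 3, DRG peak replicate 2 and nerve peak replicate 2. Perineurial genes were at -0.285 and -0.717 without nerve peak replicates 2 and 3. Satellite glia were at -0.0950 without DRG peak replicate 1, and at -0.315, 0.0107 and -0.341 without nerve peak replicates 1, 2 and 3. With an estimated correlation the adjusted p of these 20 lists was 0.106 to 0.664. Some calls were lost without 1 library. Without DRG no disease replicate 1 the adjusted p was 0.0698 for perineurial genes. Without DRG no disease replicate 2 it was 0.0541 for antigen presentation, 0.122 for cytokines, 0.0526 for erythroid, 0.105 for neutrophil and 0.0541 for node genes. Without DRG no disease replicate 3 it was 0.153 for mitochondrial RNA and 0.0504 for node genes. Without DRG peak replicate 1 it was 0.0696 for perineurial genes. Without DRG peak replicate 2 it was 0.0804 for antigen presentation, 0.128 for cytokines, 0.129 for mitochondrial RNA and 0.102 for node genes. Without DRG peak replicate 3 it was 0.0668 for cytokines, 0.0671 for erythroid, 0.119 for neutrophil and 0.109 for perineurial genes. Without nerve no disease replicate 1 it was 0.0557 for antigen presentation, 0.0657 for erythroid, 0.0524 for neutrophil and 0.16 for non-peptidergic genes. Without nerve no disease replicate 2 it was 0.0642 for node and 0.0558 for perineurial genes. Without nerve no disease replicate 3 it was 0.254 for cytokines, 0.0689 for mitochondrial RNA, 0.059 for neutrophil, 0.059 for node and 0.0919 for perineurial genes. Without nerve peak replicate 1 it was 0.0695 for cytokines, 0.078 for neutrophil and 0.0596 for perineurial genes. Without nerve peak replicate 2 it was 0.0786 for antigen presentation, 0.211 for mitochondrial RNA and 0.0864 for node genes. Without nerve peak replicate 3 it was 0.0657 for antigen presentation, 0.14 for cytokines and 0.142 for neutrophil genes.

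By gene, the log2 difference was 4.42 for Cthrc1, 4.08 for Ckap2, 3.94 for Cd22, 3.49 for Iqgap3 and 2.23 for Mki67, with larger rises in nerve. It was -6.81 for Scn10a, -5.23 for Mrgprd, -4.81 for Calca, -2.43 for Pvalb, -2.19 for Atf3 and -1.60 for Prx. Pvalb is also a gene of fast muscle. Muscle genes held 0.0225% to 0.0692% of counts in no disease nerve and 0.00117% to 0.00558% in peak nerve, so muscle may add to its difference. The channel Trpa1 (ENSMUSG00000032769, chromosome 1, 14872648 to 14918862), the receptor subunit Chrna6 and the receptor Mrgprb5 had no count in nerve at peak, which put them at least 39.6-fold, 30.2-fold and 14.2-fold below no disease nerve, with adjusted p = 0.026, 0.022 and 0.0106 for the difference. These bounds were 5.95-fold, 7.86-fold and 5.28-fold without nerve no disease replicate 1, 26.3-fold, 20.1-fold and 9.44-fold without nerve peak replicate 1, and 24.4-fold, 18.6-fold and 8.77-fold without nerve peak replicate 3. The adjusted p of Mrgprd was 0.0948 without nerve no disease replicate 1 and 0.0503 without nerve peak replicate 2, and that of Trpa1 was 0.114, 0.0523 and 0.0506 without nerve no disease replicate 1 and nerve peak replicates 1 and 2. For Pvalb it was 0.0659, 0.0669, 0.073, 0.0728 and 0.0715 without DRG no disease replicates 1 and 2, DRG peak replicate 1, nerve no disease replicate 2 and nerve peak replicate 3.

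Neuronal transcripts were lower in nerve at peak than with no disease. A larger share of other cells at peak, diluting every resident transcript, cannot be decided by the myelin list. Its median of -0.172 (quartiles -0.407 to 0.14) lay above that of 27 neuronal members (-2.62, quartiles -5.28 to -1.44), but these were chosen because they fell. At peak the mean log2 CPM fell from 5.73 to 4.78 for endothelial, 6.82 to 6.10 for perineurial and 6.30 to 5.71 for mural genes. It rose from 6.76 to 7.14 for glial lineage, 6.65 to 6.95 for satellite glia and 8.90 to 9.39 for matrix genes. Resident lists thus did not move alike, and dilution as part of the pattern stays open. DRG material in the no disease nerve libraries may account for part of the pattern: on average they held 290 abundant DRG genes above the peak level at a median of 1.80% of the DRG level, with an upper over lower quartile of 1.53, and 11 transcription factors and nuclear RNAs, not known as axonal, stood at 0.918 times that share. No disease replicate 1 dominated, with 4.85% against 1.64% and 1.10% before the peak level was taken off. Over the peak level the quartile ratio was 1.58 in replicate 1 but 2.57 and 24.6 in replicates 2 and 3, where an even share of DRG material needs at most 2, and the nuclear genes stood at 0.84, 1.02 and 1.23 times the share. Before the peak level was taken off, the nuclear genes stood at 0.715, 0.585 and 0.477 times the share. In peak nerve they stood at 0 to 0.134 times the share, so part of the full share need not be DRG material. The shares of replicates 2 and 3 over peak were small (0.898% and 0.373%), so for them DRG material cannot be told apart from other sources, and the genes were chosen on a low level in peak nerve. A loss of axonal transcripts at peak stays open and was not tested.

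Myelin genes were higher in DRG at peak and at recovery than with no disease. Nerve tissue with its fat, carried along with the DRG, is argued against by abundant nerve genes outside the list. At peak, 37 such genes gained 0.538% of their nerve level where the myelin list needs 19.4%, a ratio of 0.0278. At recovery, 49 gained 0.468% where it needs 14.4%, a ratio of 0.0326. These genes were chosen at 16 times their DRG level or more, and many, such as Adipoq, Plin1 and Lep, are genes of fat cells. Nerve tissue without fat is therefore not covered by them. A lower share of neurons, raising every other cell type, is argued against at peak by 26 satellite glia, endothelial and perineurial members. Their median was -0.114 at peak and 0.167 at recovery, against 0.829 and 0.945 for myelin. At recovery a lower share of neurons stays open for part of the rise. There the mean log2 CPM rose over no disease from 3.85 to 4.23 for endothelial, 4.32 to 4.54 for perineurial and 4.14 to 4.56 for mural genes. Satellite glia genes fell from 6.85 to 6.51, which lowers the pooled median. A change in myelinating cells of the DRG with disease, spinal roots, or nerve without fat taken with the ganglia stays open, and none of them was tested. The list for glia of the central nervous system had a mean log2 CPM of 2.08 in DRG with no disease. It was at 2.90 at peak, with 3.77 in replicate 1 against 2.59 and 2.35 in replicates 2 and 3, and at 1.74 at recovery.

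DRG recovery replicate 1 stood apart from recovery replicates 2 and 3. A no disease library under the recovery label is argued against by tests that held out each no disease library in turn and took the genes called higher at peak against the other 2. The median log2 level of these genes over those 2 libraries was 0.568, 0.545 and 0.612 in recovery replicate 1, against -0.0364, 0.102 and 0.114 in the library held out and 0.657 to 0.784 in the other recovery libraries. Other cells diluting the neurons in replicates 2 and 3 may account for part of it, since 91.8% of 73 neuron-enriched genes were higher in replicate 1, by a median of 0.329. A bias with transcript length from RNA quality cannot be told apart from it, since the Spearman correlation of length with the ratio over 11933 genes was 0.219, against -0.223 to 0.135 for the other DRG libraries, between the bounds set for either reading. A different degree of recovery in this sample stays open and was not tested.

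For the comparisons within a tissue, 6 libraries make 10 splits, which are too few for a share under 0.05. In nerve, 4355 genes were called at peak, 164 at recovery and 2966 between them, and the highest of the other splits called 0 each time. In DRG, 1257 were called at peak and 523 at recovery, and the highest of the other splits called 0. Between peak and recovery DRG, 23 genes were called, but the split of recovery replicate 1 with peak replicates 1 and 2 against the other 3 libraries called 1085, which points to a structure of the samples other than stage. Blood genes followed that split. The erythroid list held 0.00493% to 0.0112% of counts in the first 3 libraries and 0.0299% to 0.0594% in the other 3. The neutrophil list held 0.00917% to 0.0220% and 0.0469% to 0.0747%. Whether blood accounts for the 1085 calls was not tested. The real count of genes was reached in 1 of the 10 splits, the real one, for the first 5 comparisons and in 2 for the last. The lists called were 13, 19 and 15 in nerve and 14, 21 and 16 in DRG, and the highest of the other splits called 17, 19, 19, 18, 21 and 20. As many lists were called in 10, 2, 6, 6, 2 and 4 of the 10 splits. In every comparison at least 1 split that mixed the stages thus called as many lists as the real one. The number of lists called by camera with the preset correlation therefore does not tell stage from other groupings of the libraries. The overlap of peak and recovery calls was 140 genes in nerve and 326 in DRG, and the highest of the other 99 drawn splits shared 0, so that 1 of 100 was as large in each tissue. In each of the 99, at least 1 of the 2 comparisons called no gene with edgeR, so no gene could be shared, and these splits do not exclude chance.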

How the results depend on the processing

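The fit without the ribosomal RNA genes and the fit with a blood score covariate were chosen after seeing the data, and the listed rounding of fractional counts was not run because the table holds whole counts. Depth limits the calls at low counts. The counts of nerve at peak stayed within 1.5 times under 15 of 17 alternatives for higher genes and 14 of 17 for lower genes, whereas those at recovery moved under most. Where a count moved for another reason than a stricter threshold or fewer libraries, the cause was not tested.

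Counts of genes higher and lower are given in the order of nerve at peak, nerve at recovery, nerve recovery against peak, then the same for DRG, then the tissue difference. At adjusted p under 0.01 they were 1292 and 773, 15 and 3, 295 and 705, 207 and 104, 3 and 0, 0 and 0, and 473 and 506, and the overlaps were 14 in nerve and 1 in DRG. At an absolute log2 fold change of at least 1 they were 909 and 688, 63 and 35, 274 and 623, 223 and 22, 131 and 1, 3 and 10, and 444 and 736. The zeros of DRG recovery against peak stand beside 2372 genes at unadjusted p under 0.05. The other settings are named where a count moved by over 1.5 times. With all 18 libraries in 1 fit, nerve peak gave 3026 lower, nerve recovery 170 and 145, nerve recovery against peak 1960 higher, and DRG recovery 76 lower. With DESeq2, nerve recovery gave 283 and 267, DRG peak 843 lower, DRG recovery 918 and 588, and DRG recovery against peak 101 and 191. With limma-voom, nerve recovery gave 55 and 35, and DRG recovery against peak 1 and 11. With no filter, nerve recovery gave 176 and 140, DRG recovery 674 higher, DRG recovery against peak 46 and 92, and the tissue difference 999 lower. With the compared groups alone, nerve recovery gave 130 lower, DRG recovery 182 and 34, and DRG recovery against peak 0 and 0. With the blood score, DRG peak gave 1542 and 1153, and DRG recovery against peak 82 and 211. Lists called were 2, 0, 0, 0, 0, 0 and 0 with an estimated correlation, and with fry 0 for nerve recovery, 5 for DRG peak, 8 for DRG recovery, 0 for DRG recovery against peak and 10 for the tissue difference. Calls of lists described in these texts that fry ended, beyond those named there, were in nerve at peak sterol synthesis (0.0971) and erythroid genes (0.0863), and in nerve at recovery macrophage, proliferation, lipid handling and muscle genes (0.0545 each) and pan-neuronal genes (0.44). In nerve recovery against peak they were antigen presentation (0.0555) and channels (0.118), in DRG recovery interferon (0.187) and satellite glia genes (0.0523), and in DRG recovery against peak injury (0.0605) and antigen presentation genes (0.271). In the tissue difference they were antigen presentation (0.116), cytokines (0.0834), endothelium (0.0591), erythroid (0.0794), mitochondrial RNA (0.224), neutrophils (0.116), non-peptidergic (0.0949), pan-neuronal (0.0591) and sterol synthesis genes (0.0794).

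With a replicate block, DRG recovery gave 66 lower and DRG recovery against peak 0 and 4. The replicate numbers were not taken to show paired samples: within a tissue, libraries of the same number in different stages correlated at -0.0413 to 0.137 in nerve and -0.329 to 0.281 in DRG after group means were removed, over 0.1 in 3 of 9 and 2 of 9 cases, and a library's best match had its number in 13 of 18 and 6 of 18.

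Without 1 library, the lowest and highest counts of genes higher and lower were 1658 to 2561 and 1320 to 2191 for nerve peak, 13 to 79 and 0 to 65 for nerve recovery, and 429 to 1621 and 819 to 2145 for nerve recovery against peak. In DRG they were 195 to 473 and 119 to 307 at peak, 2 to 1758 and 0 to 1864 at recovery, and 0 to 579 and 0 to 1175 for recovery against peak. For the tissue difference they were 752 to 1367 and 1028 to 1729, and the overlaps were 12 to 247 in nerve and 2 to 1251 in DRG. Lists called were 15 to 18, 15 to 22, 14 to 16, 13 to 19, 19 to 26, 12 to 19 and 15 to 20.

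Signs turned for genes that were not called and for 1 called list, given here with the range when 1 library was left out. In DRG recovery against peak, Calca ranged from -0.0279 (without peak replicate 2) to 0.129, and was at -0.00584 without peak replicate 3. Mki67 ranged from -0.235 (without recovery replicate 2) to 0.405, with -0.167 without peak replicate 2 and -0.169 with the blood score. Mrgprd ranged from -0.126 to 0.0454 (without recovery replicate 2), with 0.0292 without peak replicate 2. In DRG recovery, the neutrophil list, which camera called, had a median of -0.00997 with the blood score, which is built in part from that list. Its median ranged from 0.820 (without recovery replicate 2) to 1.77 (without recovery replicate 1). Tubb3 in DRG peak ranged from -0.155 to 0.0258 (without peak replicate 1). In nerve peak, Sox10 ranged from -0.229 (without peak replicate 3) to 0.277, with -0.192 without no disease replicate 1 and -0.0227 with all 18 libraries in 1 fit. Tubb3 ranged from -0.594 to 0.798 (without no disease replicate 1), with 0.0401 with limma-voom and 0.0400 with the replicate block. In nerve recovery, leaving out no disease replicate 1 turned Calca (-1.94 to 0.316), Mrgprd (-2.42 to 0.542) and Prx (-0.0617 to 0.326). Tubb3 ranged there from -0.307 (without no disease replicate 3) to 1.08, with -0.215 and -0.244 without no disease replicate 2 and recovery replicate 1. Tubb3 in nerve recovery against peak ranged from -0.0188 (without recovery replicate 1) to 0.499. In the tissue difference it ranged from -0.629 to 0.830 (without nerve no disease replicate 1), with 0.0606 with limma-voom and 0.0389 with the replicate block.

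Named genes kept their direction and side of the threshold in 1633 of 1792 values for nerve peak, 308 of 435 for nerve recovery, 1140 of 1303 for nerve recovery against peak, 857 of 1008 for DRG peak, 508 of 800 for DRG recovery, 255 of 368 for DRG recovery against peak and 1523 of 1819 for the tissue difference. Most others fell short of the threshold in the same direction. Called lists did so in 127 of 143, 157 of 209, 127 of 165, 134 of 168, 208 of 252, 136 of 192 and 273 of 340.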

Other observations

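Beyond the groups described above, vessel and barrier genes were lower in nerve at peak. Of 11 endothelial genes 7 fell (9 over the list alone, median -0.86), with the junction protein Cdh5 at -1.01 ± 0.22, and of 5 perineurial genes 4 fell (4, median -0.77), with the glucose transporter Slc2a1 at -1.12 ± 0.18. For both lists camera gave adjusted p = 0.000191 and 0.00596, and with an estimated correlation the adjusted p was 0.612 and 0.579. Of 8 mural genes 1 rose and 3 fell (1 and 3, median -0.62, camera adjusted p = 0.067), and of 7 node and paranode genes 2 fell (2, camera adjusted p = 0.35). Antigen presentation genes fell for 6 of 15 members (6, camera adjusted p = 0.0814), with Cd74 at -0.94 ± 0.20. Of 21 cytokine genes 5 rose and 6 fell (6 and 8, camera adjusted p = 0.701), with Cxcl10 at 4.27 ± 0.37. Of 12 immediate early genes 2 rose and 5 fell (2 and 7, camera adjusted p = 0.067), and of 17 p53 targets 5 rose and 2 fell (7 and 2, camera adjusted p = 0.262), with the receptor Eda2r at 1.11 ± 0.16. Satellite glia markers split, with 3 of 10 higher and 3 lower (camera adjusted p = 0.0859), and the potassium channel Kcnj10 rose by 4.12 ± 0.21. Glial lineage genes rose for 5 of 10 members (5 and 1 lower over the list alone, camera adjusted p = 0.0622), with Chl1 at 1.13 ± 0.16. Of 5 erythroid genes 3 fell (5, camera adjusted p = 0.0197, and 0.612 with an estimated correlation), and the list was not called without no disease replicate 1 (adjusted p = 0.0505). Camera gave no call for the lists of T and NK cells (adjusted p = 0.0937), B cells (0.171), neutrophils (0.593), mast cells (0.661), interferon response (0.992), adipocytes (0.067), glia of the central nervous system (0.67), stress response (0.622), mitochondrial RNA (0.369), large-diameter neurons (0.0526), non-peptidergic nociceptors (0.0523), proprioceptors (0.988), low-threshold mechanoreceptors (0.558) and C-fibre neurons (0.992).

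From peak to recovery in nerve, mitochondrial RNA fell for 7 of 11 members (7, median -0.50, camera adjusted p = 0.00104, and 0.607 with an estimated correlation), with mt-Nd6 at -0.94 ± 0.15. In DRG at peak, camera also called higher the cytokine list (2 of 15 members rose, 9 over the list alone, adjusted p = 2.45e-06), proliferation (1 of 27, 1, 6.22e-05), lipid handling (4 of 16, 4, 0.0103) and glial lineage genes (1 of 10, 6 and 1 lower, 0.0222). With an estimated correlation the adjusted p was 0.404, 0.715, 0.479 and 0.404. The glial lineage call was lost without no disease replicate 1 (adjusted p = 0.07) and peak replicate 2 (0.0518). With fry the cytokine (0.063), proliferation (0.219) and lipid handling (0.0754) calls were lost. In DRG at recovery, endothelial genes were higher than with no disease for 3 of 11 members (4, median 0.37, or 0.23 without recovery replicate 3, camera adjusted p = 7.4e-05, and 0.268 with an estimated correlation). The claudin Cldn5 (1.10 ± 0.19) was among them, and its adjusted p was 0.125, 0.103, 0.107 and 0.0985 without no disease replicates 1 and 2 and recovery replicates 2 and 3. Interferon response genes were called higher there by camera (median 0.76, adjusted p = 1.95e-05, but 0.419 with an estimated correlation and 0.187 with fry), with 1 of 20 members passing edgeR's test, and the median was 0.47 without no disease replicate 2 and 0.29 without recovery replicate 3. Satellite glia genes were called lower (median -0.33, adjusted p = 3.39e-05, but 0.222 with an estimated correlation and 0.0523 with fry), with 1 of 10 members passing. Camera also called higher there the proliferation (2 of 27 members, 7 over the list alone, adjusted p = 6.6e-08), matrix (3 of 17, 7, 6.79e-07) and mural lists (1 of 8, 3, 0.00279), with an estimated correlation at 0.388, 0.381 and 0.338 and with fry at 0.117, 0.117 and 0.0719. It called lower the sterol synthesis list (median -0.09, or -0.15 without recovery replicate 1, adjusted p = 0.0136), but not with an estimated correlation (0.376), fry (0.0719) or the blood score (0.0535), and none of 22 members passed edgeR's test, with 6 lower at unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom.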
